A study of Homo sapiens with 6 samples.

How the data were processed

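Poly(A) RNA of 6 samples of RKO cells, 3 with the empty vector (EV) and 3 overexpressing Cx43 (OVER43), was made into Illumina TruSeq RNA libraries, per the labels' protocols. The authors deposited 2 tables, of 63563 genes and of 251748 isoform entries, made with Cuffdiff (version not given), per the submitters' processing notes. The aligner and the strand of the reads are not given in the sources used here. Per the file headers and values, the deposited tables hold 1 FPKM value per library and the authors' mean FPKM per group. The deposited log2 fold change is that of EV over OVER43. The authors' test statistic, a score, and the deposited p-values and q-values are those of Cuffdiff and enter only the comparison with the authors' deposited table. Cuffdiff scales the libraries to each other, and 0 per-library columns were left unused.

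The submitters' notes name hg38, but the loci of the deposited tables are hg19 positions: of 52335 gene IDs shared with GENCODE 29 on GRCh38, 271 share a start or end with it and 8452 overlap it. All coordinates are those of the deposited tables, as hg19, and a locus can be a bundle of overlapping genes. The reference served for gene names, gene types, transcript length and GC content alone. A symbol was found for 52178 of the 63563 gene IDs, and 1356 genes were named by the deposited symbol only. Cuffdiff gave no estimate for 9 genes of very high depth, EEF1A1, MT-CO1 and MT-ND4 among them, which are listed at 0, and failed for 10 others; these 19 genes were left out. An exact 0 can therefore be a missing estimate. Core genes outside these 19 also read near 0, so a low value need not mean low expression. The glycolysis gene PGK1 stood at 0.0061 FPKM in OVER43 and 0 in EV. The ribosomal protein gene RPS9 stood at 0.024 and 0.080 FPKM, and the respiratory chain gene COX7B at 0 in both groups. Of the isoform entries, 52414 carry a gene ID and span the whole gene with its introns. They were used as a proxy for unspliced RNA, in which genomic DNA and leaked exon reads are not excluded.

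Columns were matched to groups by their names. They carry the numbers 0 to 2 where the labels number the replicates 1 to 3, so a column stands for a library of its group and not for a given sample. Counts had been assumed as a possible unit before the data were examined; the tables hold FPKM, so the planned test for FPKM was used. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested with limma 3.58.1 (R 4.3.3; trend and robust options) on log2(FPKM + 1), with group as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05. Transcripts were tested in the same way. Gene lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, with GJA1 left out; estimated correlations and fry were alternatives. Another 4 lists had fewer tested members. The 31 lists cover gap junctions, Wnt targets and components, TGF-β targets and components, mesenchymal, epithelial, protease, adhesion, cell cycle, p53, interferon, antigen presentation, NF-kB, MAPK, YAP, ATF4, unfolded protein response, heat shock, hypoxia, cholesterol, respiratory chain, mitochondrial genome, ribosomal protein, histone, stem cell, colon differentiation, fibroblast, leukocyte, endothelial and drug resistance genes. The lists, the tests of genes, transcripts and lists, and the rule for named genes were fixed before the data were examined. The segment analysis was added afterwards.

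The named genes are GJA1; the 12 largest changes in each direction and the 8 smallest adjusted p in each direction, among called genes with no overlap between groups, a mean of at least 1 FPKM and a symbol; up to 4 called members per list, the 2 highest and 2 lowest; and CTNNB1, MYC, CCND1, AXIN2, TGFB1, SMAD7, CDH1 and VIM whatever their result. Some genes that meet this rule are not reported here. Segments were found per chromosome by a permutation test for changes of the mean fold change along tested genes, limited to 1 in either direction (200 permutations, at least 15 genes), and called shifted where the median lay 0.15 or more from that of all genes.

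No counts were used, since the tables hold none. Depth was read from low FPKM values (under 10 fragments) of genes with 1 isoform, which step by the value of 1 fragment; 344 to 372 such values per library gave 42.4 to 52 M fragments on the FPKM scale. Replicates were not copies of each other: chi-square per gene between libraries of a group was 3.01 to 17.6. Tested on simulated data with 200 changed genes in this comparison (12009 genes), the procedure recovered 59% of changes of 0.5 and 88% of changes of 1 on the log2 scale with 5 false calls. For transcripts (29229) it recovered 11% and 31% with 2 false calls. Alternatives were TMM (own implementation), quantile and equal-sum scaling, no filter or at least 5 FPKM, a pseudocount of 0.1, a block by column number, leaving out each library, and leaving out shifted segments. Files were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9.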

Results

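Poly(A) RNA was sequenced from RKO cells, a human colorectal cancer line, stably transfected with a pcDNA3.1 expression vector. The empty vector gave the EV group (3 libraries), and the vector carrying the cDNA of the gap junction protein Cx43, encoded by GJA1, gave the OVER43 group (3 libraries). The only comparison of the design, OVER43 against EV, asks which transcripts differ in these cells when Cx43 is overexpressed, in a series whose title concerns nuclear Cx43, β-catenin and TGF-β. Low FPKM values (fragments per kilobase and M fragments) were whole multiples of the value of 1 fragment, with 100% of them within 0.1 of a whole number. These steps placed the OVER43 libraries at 49.1, 47.7 and 46.8 M fragments and the EV libraries at 52, 42.4 and 46.8 M, on the scale of the deposited FPKM. The FPKM of a library summed to 554456 to 566947 in OVER43 and to 500546 to 509175 in EV. Values are given below as mean FPKM ± SD (n = 3 libraries per group), OVER43 before EV, and fold changes are differences of log2(FPKM + 1), which understates the change of weakly expressed genes.

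GJA1 was measured first, as a check of the labels. It stood at 24.7 ± 1.44 FPKM in OVER43 and 0.348 ± 0.0469 FPKM in EV, a 71.0-fold ratio of means (log2 fold change 4.25, SE 0.081, limma adjusted p = 3.22e-08). The OVER43 libraries read 23.2, 26.0 and 24.9 FPKM and the EV libraries 0.2999, 0.351 and 0.394 FPKM. An exact two-sided permutation test of these 6 values gave p = 0.1, the smallest that 10 splits allow. The gene (ENSG00000152661) lies on chromosome 6 at 121756838 to 121770873 (hg19 positions, as in the deposited tables). Nearly all of its signal was on the spliced transcript, at 24.7 ± 1.44 and 0.348 ± 0.0469 FPKM, and the entry spanning the whole gene stood at 0.00321 ± 0.00407 and 0.000696 ± 0.00120 FPKM.

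Outside GJA1, the largest losses in OVER43 were of C19orf33, MAP1LC3C (an LC3 family protein of autophagy), S100A10 (the partner of annexin A2) and ADTRP. C19orf33 fell from 46.2 ± 0.952 FPKM in EV to 0.301 ± 0.219 FPKM in OVER43 (log2 fold change -5.19), and ADTRP from 34.1 ± 0.2202 to 0.330 ± 0.0637 FPKM (-4.72). MAP1LC3C stood at 3.57 ± 0.414 against 138.1 ± 5.31 FPKM (-4.93) and S100A10 at 0.940 ± 0.184 against 55.7 ± 2.83 FPKM (-4.87). Pseudogenes aside, the largest gains were of SP140, a nuclear body protein, at 57.3 ± 1.92 against 2.30 ± 0.192 FPKM (4.14), and ARHGAP29 at 73.0 ± 3.24 against 6.88 ± 0.282 FPKM (3.23). The limma adjusted p of these 6 genes lay between 1.30e-08 and 6.41e-08.

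Further strong losses included RGS4, a regulator of G protein signalling (83.0 ± 7.76 against 537.4 ± 6.79 FPKM), TTN (6.07 ± 0.348 against 42.2 ± 2.77), GNAL, a G protein alpha subunit (1.33 ± 0.0710 against 13.1 ± 0.664), the scaffold AKAP12 (1.34 ± 0.121 against 17.1 ± 0.665), moesin, MSN (0.229 ± 0.0484 against 7.69 ± 0.332), and the ephrin EFNB2 (15.7 ± 0.493 against 75.5 ± 2.39). CCN1, a matricellular protein, fell from 66.4 ± 1.12 to 20.4 ± 0.541 FPKM. CEP170 and SDCCAG8, neighbours on chromosome 1 at 243287730 to 243418650 and 243419320 to 244014381, fell together, from 9.44 ± 0.806 to 0.0897 ± 0.0453 FPKM and from 8.91 ± 0.828 to 0.523 ± 0.345 FPKM; CEP170 has a pseudogene copy that can share its reads. ESM1 was listed at 0 in the 3 OVER43 libraries and at 5.02, 5.40 and 4.42 FPKM in the EV libraries. METTL7B fell from 63.9 ± 2.85 to 13.9 ± 0.342 FPKM, on a chromosome 12 segment whose genes had a median log2 fold change of -0.20.

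Among the other gains, ZNF114 rose from 3.34 ± 0.319 to 22.1 ± 1.17 FPKM and UTS2, which encodes urotensin 2, from 1.88 ± 1.33 to 10.9 ± 1.08 FPKM. RASSF8 rose from 27.2 ± 2.80 to 191.2 ± 6.13 FPKM and its neighbour LMNTD1 from 2.48 ± 0.767 to 14.8 ± 0.822 FPKM, against the median of -0.20 of their chromosome 12 segment. CALB2, encoding calretinin, rose from 95.5 ± 1.64 to 200.8 ± 4.91 FPKM, against the median of -0.15 of its chromosome 16 segment. The pseudogenes RPL39P3 (9.86, 9.78 and 9.69 FPKM, listed at 0 in EV) and RPL15P3 (33.7 ± 4.21 against 6.06 ± 0.519 FPKM) can share reads with their parent genes, which was not tested, and are uncertain. So are RCC2-AS1 (3.64 ± 0.544 against 0.449 ± 0.777 FPKM), since the strand of the reads is not given, and the small nucleolar RNA SNORA23, listed at 0 in EV and at 14.2, 1.81 and 4.24 FPKM in OVER43. The SNORA23 call ended without EV library 0 (limma adjusted p = 0.0507) or EV library 1 (0.0526), and without the filter on low values (0.0734).

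Across the transcriptome, 5600 of 12205 tested genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 3462 higher and 2138 lower in OVER43. Of these, 239 changed at least 2-fold, 77 higher and 162 lower, and 1514 changed by less than 1.2-fold. The groups did not overlap in 6870 genes (56.3%), where chance gives 10%. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.988 to 0.992 within groups and 0.970 to 0.972 between them. The first principal component separated the groups and held 65.3% of the variance. On the second (11.1%) EV library 2 stood apart, at -17.2 against 9.003 and 8.033 for EV libraries 0 and 1. The share of changed genes that were higher, 61.8% as deposited, was 50% (2685 higher, 2685 lower) after TMM scaling, 51.2% (2557, 2434) after quantile scaling and 34.3% (1867, 3579) with each library scaled to the same FPKM sum. The median log2 fold change of all genes was 0.05 as deposited and -0.08 with equal sums. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

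**Figure D1:**
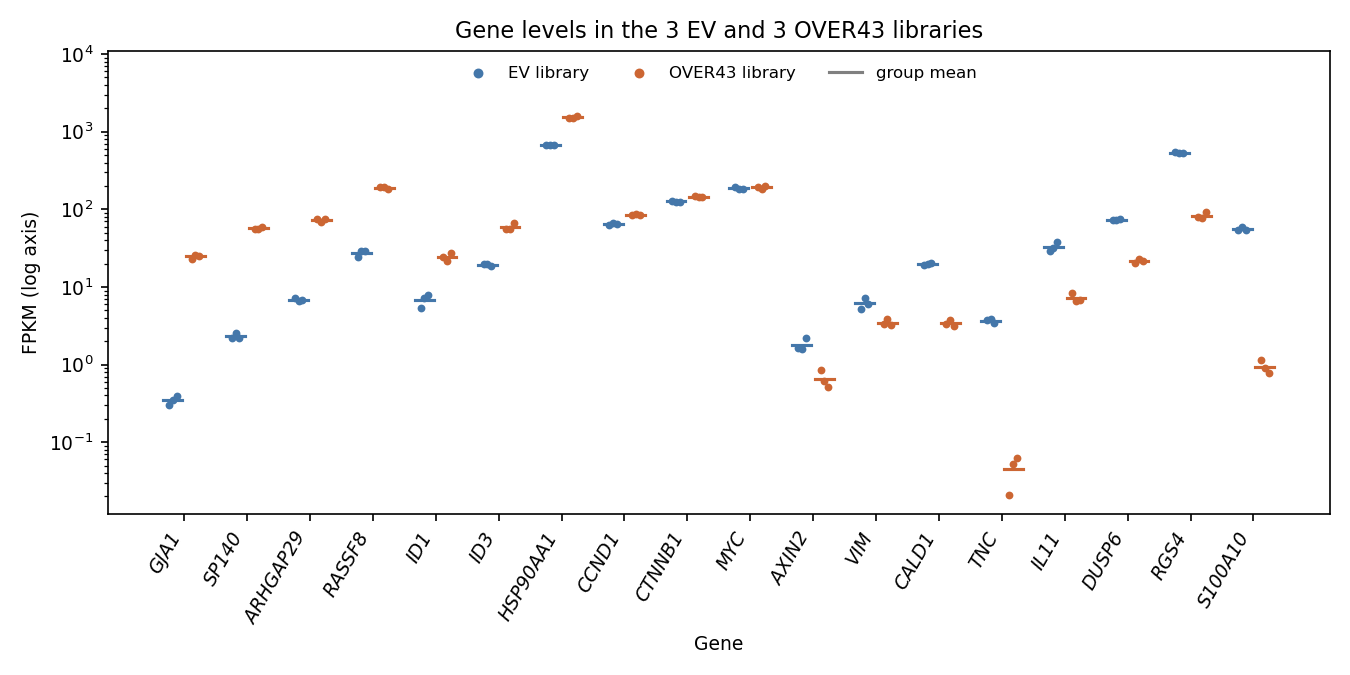
FPKM (log axis) of 18 named genes in the 3 EV and 3 OVER43 libraries, 1 point per library, with a bar at each group mean. GJA1 reads 0.2999 to 0.394 in EV and 23.2 to 26.0 in OVER43, while MYC and CTNNB1 lie close together in both groups.

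Of the β-catenin/TCF target genes, most that changed fell in OVER43. AXIN2, the negative feedback regulator of the pathway, fell from 1.81 ± 0.332 to 0.659 ± 0.170 FPKM (log2 fold change -0.76, SE 0.14, limma adjusted p = 0.00299), and NKD1, another feedback inhibitor, from 3.71 ± 1.06 to 1.63 ± 0.277 FPKM, a call lost without the filter on low values (adjusted p = 0.0560). EPHB2, a receptor of crypt cells, fell from 11.1 ± 0.659 to 6.48 ± 0.589 FPKM. CCND1, encoding cyclin D1, went the other way, rising from 65.2 ± 1.89 to 85.4 ± 0.918 FPKM (0.38, limma adjusted p = 0.000100). Of 16 tested targets, 2 rose and 9 fell (3 and 9 adjusted over the list alone), with a median of -0.39. The list lay lower than other genes (camera adjusted p = 0.0107), though not with an estimated correlation (adjusted p = 0.214) or without EV library 0 (adjusted p = 0.0638). The estimate, -0.027, was below the preset 0.01, so correlation among the members did not end the call. That setting also gives camera fewer degrees of freedom.

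CTNNB1, which encodes β-catenin, read 145.6 ± 1.51 FPKM in OVER43 and 127.0 ± 2.17 FPKM in EV (log2 fold change 0.20, limma adjusted p = 0.00101). That call depended on scaling, with -0.0062 (adjusted p = 0.879) after quantile scaling and 0.05 (adjusted p = 0.141) with equal FPKM sums. MYC read 192.5 ± 7.27 against 187.2 ± 6.48 FPKM (0.04, adjusted p = 0.429), and was lower after quantile scaling (-0.16, adjusted p = 0.00698) and with equal sums (-0.10, adjusted p = 0.0378). Of 27 tested Wnt pathway components, 6 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of 0.08 and a mean of 0.0010 (camera adjusted p = 0.857). With equal sums 3 rose and 6 fell. The Wnt secretion factor WLS (55.2 ± 1.65 against 39.7 ± 1.46 FPKM) and the adaptor DVL2 (34.2 ± 2.43 against 25.2 ± 0.348) rose, and the receptor FZD1 fell (0.860 ± 0.145 against 2.01 ± 0.252). These 3 calls held under each scaling.

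Genes of the TGF-β target list split in both directions. ID1 and ID3, inhibitors of basic helix-loop-helix factors that BMP and SMAD signals induce, rose from 6.83 ± 1.35 to 24.4 ± 2.63 FPKM (log2 fold change 1.71) and from 19.3 ± 0.662 to 59.6 ± 6.61 FPKM (1.57). Since BMP signals induce ID1 and ID3 too, their rise cannot be read as a response to TGF-β. The cytokine IL11 and the transcription factor BHLHE40 fell, from 32.8 ± 4.38 to 7.22 ± 0.893 FPKM (-2.04) and from 81.5 ± 0.963 to 28.6 ± 3.46 FPKM (-1.49). Of 19 tested targets 5 rose and 6 fell, also adjusted over the list alone, and camera found no difference from other genes (adjusted p = 0.684). The list's median (0.09) and mean (0.04) were positive while camera's direction was down.

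Of 21 tested TGF-β ligands, receptors and SMADs, 0 rose and 8 fell (0 and 8 adjusted over the list alone), with a median of -0.18. On shifted segments lay 5 of the 21, and the median of the members off them was -0.13. SMAD3, a TGF-β signal transducer, fell from 1.80 ± 0.890 to 0.278 ± 0.109 FPKM, and BMP4, a ligand that is also a β-catenin target, from 2.04 ± 0.484 to 0.201 ± 0.0652 FPKM, against the median of 0.45 of its chromosome 14 segment. The SMAD3 call was lost without the filter on low values (adjusted p = 0.0546). Camera placed the list lower than other genes (adjusted p = 0.0135), but not with an estimated correlation (adjusted p = 0.214) or without EV library 2 (adjusted p = 0.0572). TGFB1 itself read 47.9 ± 0.884 against 47.2 ± 2.43 FPKM (log2 fold change 0.02, limma adjusted p = 0.728), and its sign was negative under the 3 other scalings. SMAD7 stayed below the expression filter, at 0.612 ± 0.249 against 1.02 ± 0.0498 FPKM.

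Most mesenchymal genes that passed the expression filter fell in OVER43. CALD1, encoding the actin-binding caldesmon, fell from 19.8 ± 0.523 to 3.39 ± 0.332 FPKM (log2 fold change -2.24), the matrix protein gene TNC from 3.68 ± 0.248 to 0.0451 ± 0.0216 FPKM (-2.16), and VIM, encoding vimentin, from 6.13 ± 0.963 to 3.48 ± 0.377 FPKM (-0.67, limma adjusted p = 0.00232). TNC lies on a chromosome 9 segment with a median of -0.36 and VIM on a chromosome 10 segment with a median of -0.18. Of the 25 listed genes 10 were tested. The others, such as CDH2, FN1, SNAI2, ZEB2 and COL1A1, stayed below the filter, so the list speaks for its tested members only. Of these 10 members 1 rose and 8 fell (1 and 8 adjusted over the list alone), with a median of -0.67 and of -0.55 over the members off such segments. The 1 gain, TPM1, was not called under the 3 other scalings (adjusted p = 0.117 with TMM, 0.184 with quantile scaling, 0.568 with equal sums) or without OVER43 library 0 (0.0693) or 2 (0.0545) or EV library 0 (0.0765) or 1 (0.0705), nor without the filter on low values (0.0902). Camera gave an adjusted p of 0.00018, and 0.214 with an estimated correlation. CDH1, the epithelial cadherin gene, was below the filter at 0.258 ± 0.117 against 0.231 ± 0.147 FPKM.

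Matrix proteases and adhesion genes also lay lower. PLAU, encoding urokinase, fell from 65.3 ± 3.82 to 23.5 ± 2.46 FPKM (log2 fold change -1.44), whereas MMP14 rose from 19.8 ± 1.91 to 40.1 ± 1.37 FPKM (0.99), on the chromosome 14 segment with a median of 0.45. MMP15 fell from 3.88 ± 0.211 to 1.27 ± 0.244 FPKM, on the chromosome 16 segment with a median of -0.15, and ADAM9 rose from 35.6 ± 0.719 to 48.4 ± 0.744 FPKM. Of 14 tested proteases and inhibitors 2 rose and 8 fell (2 and 8 adjusted over the list alone; median -0.35; camera adjusted p = 0.00427, and 0.214 with an estimated correlation). Integrin ITGA3 fell from 33.2 ± 1.98 to 17.8 ± 0.598 FPKM, while the focal adhesion genes ZYX (218.3 ± 5.51 against 162.4 ± 5.96) and ILK (74.6 ± 1.09 against 56.4 ± 1.51) rose. ITGA5 fell from 43.0 ± 3.23 to 26.2 ± 0.466 FPKM on the chromosome 12 segment with a median of -0.20. Of 21 tested adhesion genes 3 rose and 9 fell, also adjusted over the list alone. The list's median was -0.13, and -0.08 over the members off shifted segments. Camera gave an adjusted p of 0.0317, and 0.260 with an estimated correlation.

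Epithelial genes were mixed. EPCAM rose from 12.5 ± 0.293 to 20.5 ± 1.54 FPKM, and MARVELD3 fell from 4.36 ± 0.302 to 1.38 ± 0.226 FPKM on the chromosome 16 segment with a median of -0.15. KRT18 (148.4 ± 0.989 against 79.4 ± 3.68 FPKM) and KRT8 (24.6 ± 1.63 against 58.7 ± 1.92) moved in opposite directions, but they share a bundle of overlapping loci on the chromosome 12 segment with a median of -0.20 and have pseudogene copies, so both are uncertain. Of 10 tested members 2 rose and 5 fell (3 and 5 adjusted over the list alone; median -0.31, and -0.05 over the 5 off shifted segments; camera adjusted p = 0.137). Among gap junction genes other than GJA1, the connexin GJC1 rose (3.17 ± 0.0469 against 1.64 ± 0.167 FPKM). Of 10 tested members 1 rose and 3 fell (2 and 4 adjusted over the list alone), and camera gave an adjusted p of 0.374, with a positive median (0.05) and a negative mean (-0.18).

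Immediate-early genes and feedback regulators of the MAPK pathway fell on balance. The ERK phosphatase DUSP6 fell from 73.3 ± 1.84 to 21.7 ± 1.54 FPKM (log2 fold change -1.71) and EGR3 from 7.60 ± 0.129 to 3.18 ± 0.417 FPKM (-1.05), while FOSL1 rose from 176.3 ± 1.08 to 225.1 ± 1.14 FPKM (0.35). Of 24 tested members 4 rose and 11 fell, also adjusted over the list alone (median -0.17; camera adjusted p = 0.00764, and 0.214 with an estimated correlation). Of 12 drug efflux and detoxification genes 1 rose and 7 fell, also adjusted over the list alone (median -0.16; camera adjusted p = 0.0242, and 0.214 with an estimated correlation), led by TXNRD1, the cytosolic thioredoxin reductase, at 128.2 ± 5.43 against 239.2 ± 0.563 FPKM. The gain, GSTP1 (491.7 ± 9.50 against 431.8 ± 13.9 FPKM), was not called after quantile scaling (adjusted p = 0.168) or with equal sums (adjusted p = 0.155).

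Heat shock genes rose together. HSP90AA1, encoding an inducible cytosolic chaperone, rose from 674.4 ± 8.07 to 1531 ± 38.9 FPKM (log2 fold change 1.18, limma adjusted p = 6.41e-08), on the chromosome 14 segment with a median of 0.45, and HSPA8, the constitutive HSC70 gene of chromosome 11, from 899.3 ± 65.0 to 1515 ± 47.9 FPKM (0.75). All 13 tested members rose, also adjusted over the list alone, with a median of 0.41 (camera adjusted p = 4.94e-06, and 0.214 with an estimated correlation). After quantile scaling 11 rose, and with equal sums 12. Endoplasmic reticulum chaperones such as CANX (351.1 ± 22.2 against 258.2 ± 8.32 FPKM) and PDIA6 (223.3 ± 4.52 against 178.5 ± 1.79) rose. HSPA5 fell (289.6 ± 2.76 against 325.9 ± 13.2), on the chromosome 9 segment with a median of -0.36. Of 21 genes of the unfolded protein response 11 rose and 2 fell (12 and 2 adjusted over the list alone; median 0.19; camera adjusted p = 0.0342, and 0.214 with an estimated correlation). The list's call ended after quantile scaling (5 higher and 4 lower, adjusted p = 0.468), with equal sums (3 and 4, 0.130), and without EV library 0 (0.0512) or EV library 2 (0.0597).

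Cell cycle genes rose as a group. TYMS, the thymidylate synthase gene, rose from 83.7 ± 5.21 to 132.5 ± 1.54 FPKM (log2 fold change 0.66) and MCM4, a subunit of the replicative helicase, from 183.6 ± 22.96 to 271.6 ± 25.5 FPKM (0.57). Of 36 tested members 26 rose and 0 fell (27 and 1 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 3.04e-05, and 0.254 with an estimated correlation). With equal FPKM sums 16 rose and 3 fell, and the median lay 0.18 above that of all genes.

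Ribosomal protein and respiratory chain genes rose by small amounts in the deposited values. RPL6 rose from 1197 ± 18.9 to 1447 ± 50.01 FPKM (log2 fold change 0.27), and RPL35 fell from 2823 ± 28.8 to 2324 ± 62.1 FPKM (-0.28) on the chromosome 9 segment with a median of -0.36. Of 48 tested ribosomal protein genes 39 rose and 2 fell, also adjusted over the list alone (median 0.15; camera adjusted p = 4.94e-06, and 0.454 with an estimated correlation). The direction depended on scaling, with 5 higher and 13 lower after quantile scaling (camera adjusted p = 0.0700, lower) and 12 and 13 with equal sums (0.426). RPL6 itself was not called after quantile scaling (limma adjusted p = 0.0504). CYC1, encoding cytochrome c1, rose from 109.3 ± 5.64 to 155.5 ± 7.70 FPKM and NDUFB8 from 135.9 ± 4.71 to 180.5 ± 6.48 FPKM. Of 36 nuclear respiratory chain genes 22 rose and 5 fell (24 and 5 adjusted over the list alone; median 0.17; camera adjusted p = 0.00685, and 0.362 with an estimated correlation), but 11 and 10 after quantile scaling (camera adjusted p = 0.792, lower) and 12 and 8 with equal sums (0.161). Of 7 tested transcripts of the mitochondrial genome 6 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.20; camera adjusted p = 0.00676, 0.394 with an estimated correlation), such as MT-ND3 at 4993 ± 68.7 against 3633 ± 131.8 FPKM. After quantile scaling 2 rose (camera adjusted p = 0.378), and with equal sums 3.

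Interferon-stimulated genes lay lower by a narrow margin. The transcription factor gene IRF7 fell from 2.51 ± 0.175 to 0.430 ± 0.144 FPKM (log2 fold change -1.30) and HERC6 from 9.95 ± 0.153 to 5.16 ± 0.421 FPKM (-0.83). Of 26 tested members 3 rose and 10 fell (4 and 10 adjusted over the list alone), with a median of -0.03 and a camera adjusted p of 0.0426, and 0.214 with an estimated correlation. The call ended after quantile scaling (adjusted p = 0.0786), with equal sums (0.0586) and without EV library 0 (0.118), EV library 1 (0.202) or EV library 2 (0.121).

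**Figure D2:**
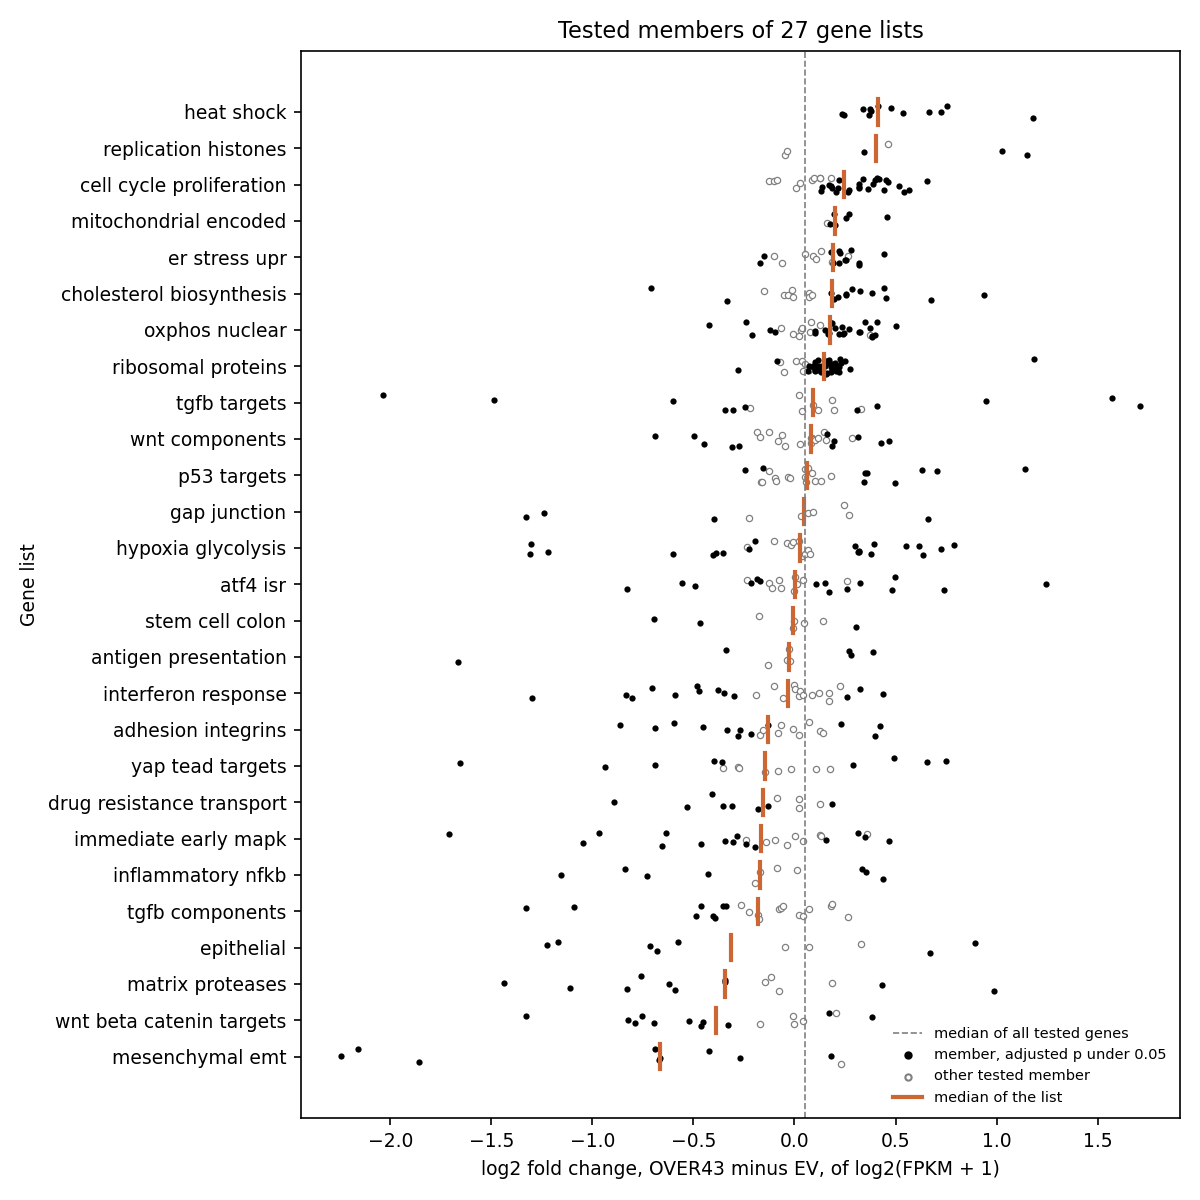
log2 fold changes (OVER43 minus EV, of log2(FPKM + 1)) of the tested members of 27 gene lists, 1 point per gene, filled where the limma adjusted p was under 0.05, with an orange bar at each list's median. The dashed line marks the median of all tested genes (0.05); heat shock genes lie at a median of 0.41 and mesenchymal genes at -0.67.

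Fold changes were not evenly spread along the chromosomes. On chromosome 14, from 21.9 to 105.9 Mb, 287 of 409 tested genes rose and 22 fell, with a median log2 fold change of 0.45. On chromosome 9, from 88.2 to 135.8 Mb, 197 of 260 fell and 7 rose, with a median of -0.36. Smaller runs lay lower on chromosome 12 (0.38 to 65.6 Mb, median -0.20), chromosome 10 (0.18 to 43.0 Mb, -0.18) and chromosome 16 (58.0 to 90.1 Mb, -0.15), and higher on chromosome 10 (43.1 to 52.4 Mb, 0.28, 28 genes). These 6 segments held 1400 tested genes, of which 879 changed and 52 changed at least 2-fold. Among genes placed on chromosomes 1 to 22 and X, they held 22.03% of those changed at least 2-fold and 11.6% of all tested. The segments were found from the same fold changes, so some excess is built in and no p is given. Without them, 4677 genes changed, 187 of them at least 2-fold.

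**Figure D3:**
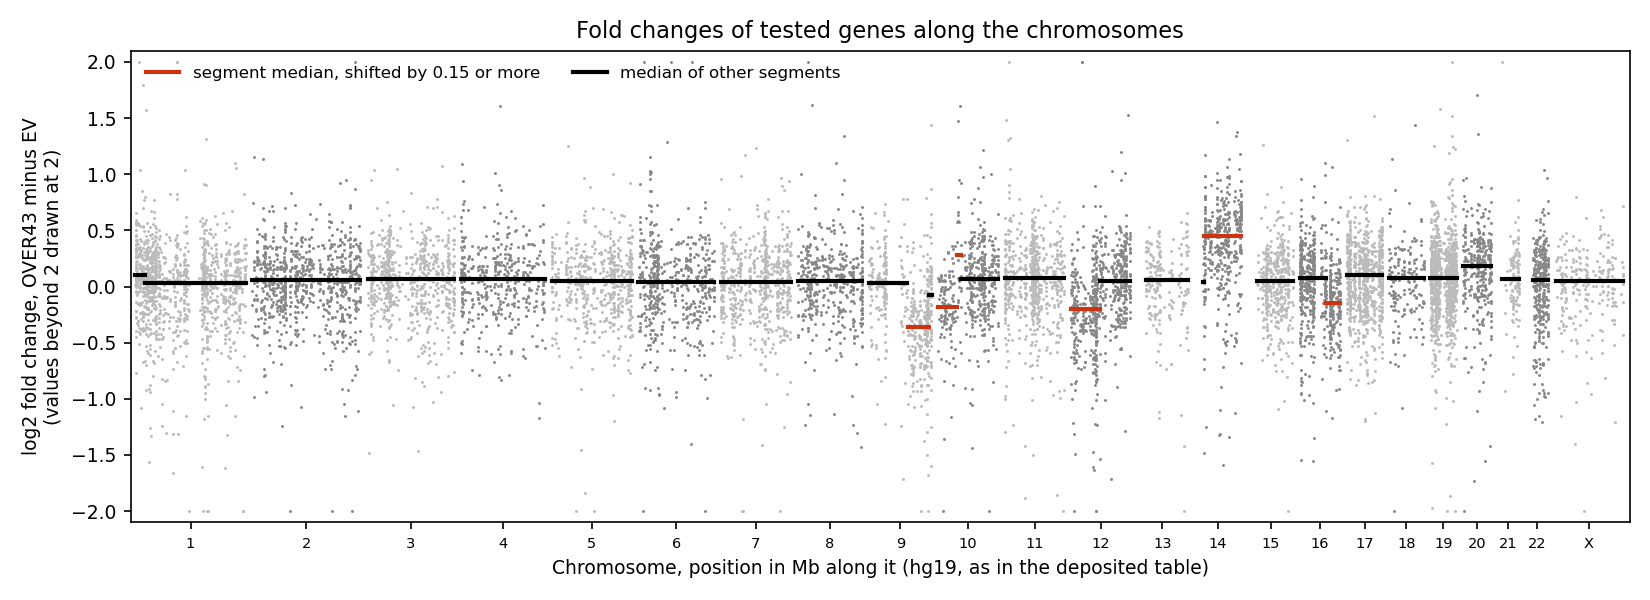
log2 fold change (OVER43 minus EV, of log2(FPKM + 1); values beyond 2 drawn at 2) of each tested gene against its position in Mb along chromosomes 1 to 22 and X, with a bar at each segment's median. Red bars mark the 6 segments shifted by 0.15 or more from the median of all genes, such as chromosome 14 at 0.45 and chromosome 9 at -0.36.

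Single transcripts mostly followed their genes. Of 30377 tested transcripts 4409 changed (limma), 2985 higher and 1424 lower, 591 of them at least 2-fold, in 3572 genes. The gene was called in the same direction for 3922 of them and in the opposite direction for 71, and for 416 it was not called or not tested. Part of this agreement is built in, since a gene's FPKM includes that of its transcripts. In 83 genes transcripts changed in both directions. In HMGN1, a nucleosome-binding protein gene chosen after its values were seen, ENST00000380749 rose from 128.4 ± 12.2 to 183.8 ± 5.56 FPKM and ENST00000288344 fell from 3.12 ± 0.951 to 0.899 ± 0.4002 FPKM. In the sorting nexin gene SNX5, chosen in the same way, ENST00000377759 rose from 3.68 ± 0.828 to 10.2 ± 1.05 FPKM and ENST00000419004 fell from 8.54 ± 1.49 to 3.66 ± 0.876 FPKM. The count of changed transcripts was lower with a library left out, at 2524, 2547 and 2567 without OVER43 library 0, 1 or 2, and at 2725, 2602 and 3482 without EV library 0, 1 or 2. Without a filter on low values it was 1726.

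The authors' deposited table marks 3393 genes as significant, 1861 higher in OVER43 and 1532 higher in EV, and 2805 isoforms. For GJA1 the authors' deposited table gives a log2 ratio of EV over OVER43 of -6.15 (q = 0.000547), and for AXIN2 1.45 (q = 0.00146). For CTNNB1 the authors' deposited table gives -0.20 (q = 0.0778), which is not marked as significant. Of the genes marked in the authors' deposited table, 3003 were tested here, and 2907 were called in the same direction by limma and 0 in the opposite one. Both results rest on the same libraries and values, so agreement in direction is largely built in. Limma called 5600 genes, so many of its calls are not among the 3393 marked.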

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

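The tests of fragment length, copy number, GC content, segment shift and shorter runs were chosen only after the pattern they bear on had been seen; the test of shorter runs replaced an earlier one whose outcome was fixed by its construction, and the interval conditions of the tests of shorter runs, GC content and fragment length were set after their values were known.

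Entries that span whole genes with their introns carried a signal on chromosome 14. They were left out of the transcript test but are part of the gene values, at a median of 1.11% of the gene's FPKM. They are therefore not an independent measurement. Their changes are differences of log2(FPKM + 0.01), over entries with a mean of at least 0.05 FPKM. On chromosome 14 their median log2 change (322 entries) was 0.27 (95% bootstrap interval 0.24 to 0.31), while entries off the shifted segments lay at -0.11.

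Genes on long runs of chromosomes 9, 10, 12, 14 and 16 moved together between OVER43 and EV. GC content bias is argued against, since after correction for transcript GC the shift of the chromosome 14 segment was 0.41 (95% bootstrap interval 0.36 to 0.44), against 0.40 before. A difference in copy number between the groups is a candidate explanation. Whole-gene shifts, of log2(FPKM + 0.01), are not on the scale of the gene shifts, of log2(FPKM + 1), so their sizes cannot be compared closely. Their bootstrap intervals resample entries with the median off the segments held fixed, and do not measure the spread between libraries. Relative to entries off the segments, the 305 whole-gene entries of the chromosome 14 segment were shifted by 0.40 (0.36 to 0.43), against 0.40 for the gene values. But shared regulation of transcription would look alike in this test, and the entries are not independent of the gene values. On chromosome 9 the whole-gene shift was -0.49 (-0.52 to -0.44), against a gene shift of -0.41. It was -0.26 (-0.31 to -0.20) against -0.25 on chromosome 12 and -0.21 (-0.27 to -0.17) against -0.20 on chromosome 16. On the longer chromosome 10 segment it was -0.25 (-0.33 to -0.21) against -0.23. On the small chromosome 10 segment (43.1 to 52.4 Mb) the whole-gene shift of 0.14 (-0.34 to 0.60) left a difference in copy number open. Whether Cx43 has any part in the runs was not tested, since the labels do not say how many independently selected lines each group holds.

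The 239 genes that changed at least 2-fold were weighed next. For those with a tested whole-gene entry, a change after transcription alone is argued against, as these entries moved too, by a median of -1.49 (78 of 162 genes lower) and 1.07 (46 of 77 genes higher), provided that leaked exon reads did not carry them. The others lack such a value. Windows of 50 genes shifted by over 0.3 held 16.5% of those placed on a chromosome, between the bounds set for and against segment gains or losses. On the shifted segments, 53.8% (28 of 52; exact interval 39.5% to 67.8%) kept a 2-fold change once the segment's shift was subtracted, which leaves the share owed to the shift open. Off them, runs long enough to shift the median of 10 neighbours (5 on each side) by 0.3 are argued against for most. Of the 184 genes, 7.61% (14 genes, CCN1, PLAU and H2BC5 among them) had neighbours shifted alike, against 0.998% of all genes off the segments. The exact interval, 4.22% to 12.4%, includes the 10% bound but lies far below the 50% the explanation needs. It takes the genes as independent, though some of the 14 share a locus start, such as PLAU and C10orf55, so the interval is too narrow. Runs of a few genes cannot be seen this way and stay open. CEP170 and SDCCAG8, neighbours that fell together, were not among the 14. An effect of Cx43 and other differences between the groups stay open as untested.

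Ribosomal protein genes, which have short mRNAs, were higher in OVER43 as deposited. A difference in fragment length between groups stays open: genes outside this list with transcripts under 800 bases lay 0.0041 above those of 2000 to 4000 bases (95% bootstrap interval -0.04 to 0.03), but among protein-coding genes alone the difference was 0.07 (0.02 to 0.16). The length offset fitted to the FPKM steps was 220 to 230 nt in OVER43 and 220 nt in EV, but it shows the length corrected for in the deposited values, which the sources used here do not call measured. Scaling stays open too, since the list's signed adjusted p was -0.0700 after quantile scaling. A biological change was not tested apart from these.

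With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of the 4 counts, 1 of 10 splits, the real one, gave as large a result. The real split gave 5600 changed genes (highest other 0, limma, with 142 to 213 genes at an unadjusted p under 0.05 against 6484), 239 at least 2-fold (0), 4409 transcripts (1) and 14 lists (6). The other splits mix EV and OVER43 in both arms, so the difference between the groups enters their spread. Low counts of genes and transcripts there are largely built in.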

How the results depend on the processing

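Tests added only after the data were seen are equal-sum scaling, the block by column number and leaving out shifted segments. GJA1 kept its direction and call in each setting in which it was tested, from 4.17 with equal sums to 5.80 with a pseudocount of 0.1, and at 4.23 to 4.28 with an EV library left out; without an OVER43 library it fell below the filter and was not tested. Changed genes numbered 4696 to 4928 with 1 library left out (2953 to 3158 higher, 1661 to 1899 lower, 181 to 229 at least 2-fold, 11 to 16 lists, 2524 to 3482 transcripts) and 3959 of 31562 without a filter. With a library left out the filter still asked for 1 FPKM in 3 libraries, and 11948 to 12083 genes were tested. Genes under 1 FPKM in OVER43, such as C19orf33 and ADTRP, then dropped out untested without an EV library. The lower counts are therefore in part due to the filter. Equal sums gave 1867 higher and 3579 lower. Genes changed at least 2-fold numbered 144 at 5 FPKM, where fewer genes are tested, and 460 with a pseudocount of 0.1, which by construction enlarges the folds of low genes. Of the 27 lists, 0 were called with an estimated correlation (4 at an unadjusted p under 0.05) and 25 with fry, which does not compare a list with other genes. Among called lists the estimate was below the preset 0.01 for Wnt targets (-0.027), TGF-β components (-0.024), proteases (-0.056) and MAPK genes (-0.018). The same held for drug resistance (-0.057), unfolded protein response (-0.026) and interferon genes (0.0021). For these, correlation among members did not end the call. For the other called lists it was higher, from 0.04 (adhesion) to 0.81 (mitochondrial genome). Transcripts changed numbered 1726 without a filter and 2137 with the block. Directions reversed for MYC (-0.0248 with TMM, -0.16 with quantile scaling, -0.10 with equal sums), TGFB1 (-0.0423, -0.10, -0.12) and CTNNB1 (-0.0062 with quantile scaling). For lists, as adjusted p signed by direction, they reversed for ATF4 (0.548) and TGF-β targets (0.437) with fry; for hypoxia with TMM (-0.953), quantile scaling (-0.572), equal sums (-0.991), the block (-0.899) and without OVER43 library 0 (-0.754) or EV library 0 (-0.837), 1 (-0.942) or 2 (-0.961), though not without OVER43 library 1 (0.996) or 2 (0.700); for the respiratory chain (-0.792) and ribosomal proteins (-0.0700) with quantile scaling; and for Wnt components with equal sums (-0.674). The cause was not tested.

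No paired analysis was possible because the columns do not carry the replicate numbers of the labels. A block by the columns' own numbers gave 5316 genes (3306 higher, 2010 lower, 240 at least 2-fold), 13 lists, 2137 transcripts and 4.25 for GJA1; the interferon list was the 1 list call it ended (0.0634). In a check of the pairing, same-numbered columns correlated at 0.017, -0.091 and 0.029, and not every library correlated best with its own number. These are not correlations of the expression levels themselves, which lay at 0.970 to 0.972 between the groups. With no counts in the tables, RLE scaling, edgeR, DESeq2 and voom were not run. Small changes can be missed with these 6 libraries: 59% of simulated gene changes of 0.5 (log2) were recovered, and 11% of such transcript changes. These shares hold for 200 simulated changes. With 5600 genes called in the real comparison the limit on the unadjusted p is looser, so its recovery is not given by them.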

Other observations

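The tests with equal FPKM sums and without the shifted segments were chosen only after the data had been seen, and so were the genes of the last paragraph.

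Sterol synthesis genes and histones lay on the higher side in the deposited values without passing the list test. INSIG1, a regulator of sterol synthesis, rose from 15.8 ± 0.694 to 31.2 ± 0.840 FPKM and SQLE, encoding squalene epoxidase, from 51.0 ± 1.95 to 82.1 ± 0.582 FPKM. Of 22 tested sterol genes 12 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.19; camera adjusted p = 0.0598, 0.214 with an estimated correlation, 0.0238 without the shifted segments and 0.0450 without OVER43 library 1). After quantile scaling 8 rose and 4 fell (adjusted p = 0.262), and with equal sums 6 and 5 (0.130). Of 6 tested replication-dependent histones, whose mRNAs mostly lack poly(A) tails, 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.40; adjusted p = 0.116, 0.0455 after quantile scaling, 0.0355 with equal sums and 0.0436 without OVER43 library 1), such as H1-2 at 63.2 ± 0.657 against 30.5 ± 1.76 FPKM.

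Stress and signalling groups split in both directions. Among p53 targets, TP53I3 rose from 8.63 ± 1.21 to 20.1 ± 1.12 FPKM and CDKN1A, encoding p21, fell from 84.7 ± 3.34 to 71.3 ± 1.76 FPKM; 7 of 24 rose and 2 fell (7 and 1 adjusted over the list alone; adjusted p = 0.485), but 7 and 4 with TMM and 7 and 7 with equal sums. Among ATF4 targets, ATF5 rose from 13.3 ± 1.72 to 32.7 ± 0.909 FPKM and CTH fell from 3.02 ± 0.573 to 1.25 ± 0.160 FPKM; 9 of 25 rose and 6 fell (10 and 6 adjusted over the list alone; adjusted p = 0.791), with a mean of 0.05 while camera's direction was down. The balance turned to 5 higher and 9 lower with TMM, 6 and 10 with quantile scaling and 5 and 10 with equal sums. Among hypoxia and glycolysis genes, ADM rose from 5.38 ± 0.549 to 10.2 ± 2.12 FPKM and SLC2A3 fell from 9.60 ± 0.511 to 3.30 ± 0.665 FPKM, on the chromosome 12 segment with a median of -0.20; 11 of 30 rose and 9 fell, also adjusted over the list alone (adjusted p = 0.993; median 0.03, mean -0.03), but 9 and 10 with TMM, 10 and 11 with quantile scaling and 9 and 13 with equal sums. Among YAP/TEAD targets, MYOF rose from 3.17 ± 0.387 to 6.05 ± 0.977 FPKM and NT5E fell from 3.23 ± 0.823 to 1.21 ± 0.352 FPKM; 4 of 17 rose and 5 fell (5 and 6 adjusted over the list alone; median -0.15; adjusted p = 0.167, and 0.0479 without the shifted segments). Among NF-kB targets, the cytokine gene LIF fell from 45.1 ± 2.53 to 19.8 ± 2.03 FPKM and NFKB1 rose from 22.3 ± 0.871 to 30.5 ± 0.310 FPKM; 3 of 11 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.137). Of 8 stem cell genes 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.381), but 0 and 3 under each of the 3 other scalings. Of 9 antigen presentation genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.739), and 2 and 3 after quantile scaling. HLA-B, measured on an alternative haplotype and so uncertain, read 29.5 ± 1.65 against 95.8 ± 4.64 FPKM.

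Markers of other cell types were scarce. The endothelial (2 tested, 2 lower), fibroblast (2 tested, 1 lower), leukocyte (1 tested, 1 lower) and colon differentiation lists (2 tested, 1 lower) had too few tested members for a list test, and adjusted over the list alone the numbers lower were 2, 1, 1 and 2. The fibroblast genes FAP, DCN and LUM stood at 0.000182, 0.000190 and 0.00243 FPKM in OVER43, and DCN and LUM at 0.000189 and 0.000791 FPKM in EV, where FAP was listed at 0.

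In 8 genes all 3 OVER43 libraries lay under 1 FPKM and all 3 EV libraries at 5 or more, and in 2 (GJA1 and RPL39P3) the reverse held. Such low values can also come from a failed estimate, which was not tested. The 8 are C19orf33, ADTRP, CEP170, SDCCAG8, MSN, RDH5 (0.474 ± 0.181 against 6.98 ± 0.443 FPKM), VAMP8 (0.271 ± 0.175 against 6.33 ± 0.762) and CCDC190 (0.181 ± 0.0879 against 5.35 ± 0.139). MAP1LC3C (chromosome 1, 242158792 to 242162375), CEP170 and SDCCAG8 lie within a short stretch of chromosome 1. Genes of chromosome 20 had a median log2 fold change of 0.18, 0.13 above that of all genes, below the limit of 0.15 for a shifted segment.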
